A study of Homo sapiens with 2 samples.

How the data were processed

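The series held 2 Fra2 ChIP-seq libraries of MCF-7 cells, 1 from cells kept for 7 days in 500 nM abemaciclib and 1 from cells in DMSO. Groups were taken from the treatment label of each library. Per the labels' protocols, cells were fixed with DSG and formaldehyde, chromatin was sonicated, and Fra2 was precipitated with a single antibody before library preparation.

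The authors deposited 1 narrowPeak list per library. Per the submitters' processing notes, BWA, MACS2 and the hg19 build were used; versions, the control library, filters and the genome size setting are not given in the sources used here. Each list gives the start, end and summit offset of a peak region. The deposited fold is the ratio of the pileup at the summit to the local background. The deposited p-value and q-value of the summit are given as −log10 values, and the deposited score is about 10 times the −log10 q. The lowest −log10 q was 1.32 in the DMSO list and 1.30 in the abemaciclib list. These values are the peak caller's own and were used to describe, rank and filter peaks within a list. Both files name chromosomes 1 to 22 and X only, and every peak ended within the hg19 chromosome length. No region was listed with more than 1 summit. Peaks were called per library.

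Depth is not stated in the files, so it was recovered. MACS2 computes the fold as (pileup + 1)/(background + 1) and p as the upper Poisson tail of the pileup at that background, so both quantities were solved for each peak. A whole pileup matched the deposited −log10 p within 0.001 for all 971 DMSO peaks and all 4724 abemaciclib peaks. On 1000 simulated peaks, 100% of pileups were recovered, and 0% of pileups scaled to non-whole values passed as whole. The backgrounds lay on steps of 0.274 fragments in DMSO and 0.244 in abemaciclib for 50.9% and 39.7% of peaks with a background below 6, where chance gives 0.146% and 0.164%. Steps of this kind arise when a deeper control library is scaled down to the ChIP library. Read as such, the controls held about 42.9 M and 44.5 M reads if the mappable genome was set to 2700 Mb; the control itself was not analysed here. The narrowest peaks were 301 bp in DMSO and 284 bp in abemaciclib, and this was taken as the fragment length, the usual minimum peak length of MACS2. Steps for a 1 kb control window computed from these lengths accounted for 62.8% and 37.1% of the remaining backgrounds, against 0.485% and 0.576% by chance. The lowest background, 1.31 and 1.14 fragments, was used as the depth of each library, and abemaciclib pileups were multiplied by 1.14 to scale them to DMSO.

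Peaks of the lists were called shared when they overlapped by at least 1 bp; the overlap code was checked against bedtools 2.31.1 on simulated intervals. Of the 780 overlapping pairs, 663 had summits within 100 bp of each other. Shares carry exact Clopper-Pearson intervals and ratios of counts carry exact binomial intervals, at the 95% level. They cover counting error only, since neighbouring peaks and reads are not independent and each treatment has 1 library. Chance overlap was taken from 1000 random placements of each list on its own chromosomes outside centromeric, stalk and variable bands, which left 92.6% of the assembly. Bands and chromosome lengths are the hg19 tables of circlize 0.4.16 and GenomeInfoDb 1.38.1. Calculations used Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and numpy 2.4.6.

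Before the data were examined, the peak classes, the amplified regions, the settings listed below and the rule for named sites were fixed. Tests of technical explanations were set partly before and partly after, as stated with them. The rule named the 10 shared and the 10 abemaciclib-only peaks with the highest abemaciclib fold and the 5 DMSO-only peaks with the highest fold. The recovery of pileups was planned too. The pileup ratio at shared sites, the higher thresholds, counts by chromosome and band, clusters, distances between sites and the sites with extreme ratios were added after the data had been seen. The settings tried, fixed with the peak classes, were stricter q and fold thresholds, other overlap definitions, lists of equal length, and leaving out the chromosomes with amplified regions. Promoter shares, motif shares and gene lists had been planned for an hg19 genome and annotation. The gene table at hand is of GRCh38, so they were not analysed here.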

Results

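Fra2 binding was profiled in MCF-7 cells, an oestrogen receptor-positive breast carcinoma line, after 7 days in 500 nM abemaciclib or in an equal volume of its solvent DMSO. Abemaciclib inhibits the cyclin-dependent kinases CDK4 and CDK6, which drive cells from G1 into S phase. Fra2, the product of FOSL2, is a FOS-family subunit of the AP-1 transcription factor. Its genomic sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) of cells fixed with the protein crosslinker DSG and then with formaldehyde. The stated aim was to examine how the drug changes Fra2 binding. Each treatment was represented by 1 library, so no difference below has a replicate check and no p-value is given. Intervals are exact 95% intervals and cover counting error only. The DMSO list held 971 peaks that covered 486 kb, and the abemaciclib list held 4724 peaks that covered 2301 kb. All positions are on hg19. A gene annotation of that build was not used here, so sites are given by coordinate and cytogenetic band.

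Fra2 was detected at many more sites in the drug-treated cells. The abemaciclib list held 4.87 times as many peaks as the DMSO list (interval 4.54 to 5.22). The median width was 434 bp in DMSO and 423 bp in abemaciclib, and the median fold over background, as the authors' peak caller gave it, was 6.06 and 5.96. The parts of the fold differed between the lists, with a median of 22 fragments at the summit over a background of 2.66 in DMSO and of 16 over 1.47 in abemaciclib. The median −log10 q was 9.05 and 6.84. More abemaciclib than DMSO peaks also passed stricter thresholds. At a −log10 q of at least 10 there were 434 DMSO peaks and 1645 abemaciclib peaks, a ratio of 3.79 (3.41 to 4.22). At a −log10 q of at least 50 there were 42 and 141, a ratio of 3.36 (2.36 to 4.86). Of those 141 peaks, 135 overlapped a DMSO peak of any strength. At that level the ratio therefore mostly counts sites present in both lists, not further sites. At a fold of at least 20 the numbers were 11 and 94, a ratio of 8.55 (4.56 to 17.7). Fold and q also depend on the local background. At shared sites the depth-scaled background was higher in DMSO, with a median ratio of 1.32, which lowers both values there. Ratios at equal thresholds therefore do not reflect the number of fragments alone. The deposited fold and p of each peak also gave back the number of fragments at its summit (the pileup) and the local background. The lowest background, which follows read number times fragment length, was 1.31 fragments in DMSO and 1.14 in abemaciclib. The library with more peaks had the lower value, at a ratio of 0.874. The recovered values correspond to about 11.7 M reads in DMSO and 10.9 M in abemaciclib, if the mappable genome was set to 2700 Mb.

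**Figure D1:**
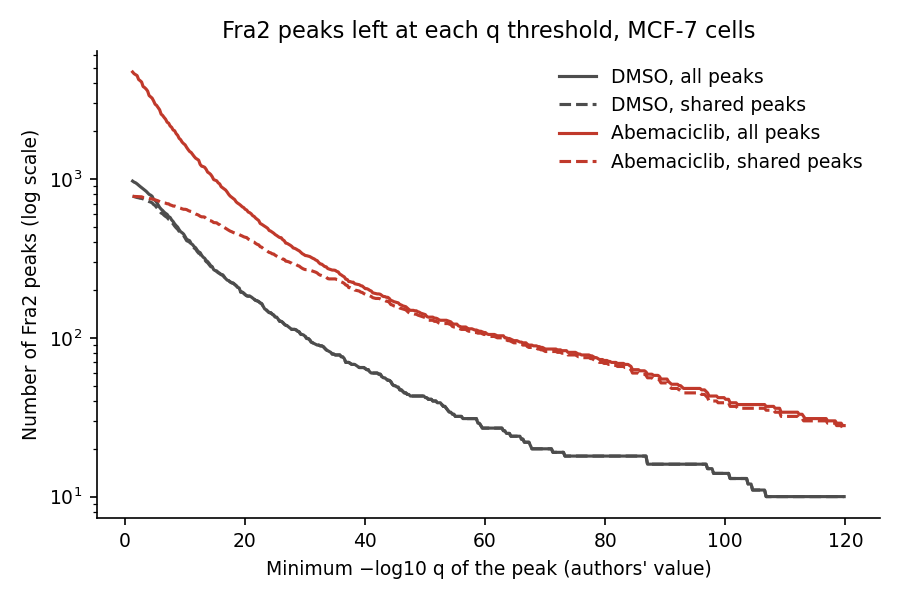
Number of Fra2 peaks (vertical axis, log scale) with at least a given −log10 q (horizontal axis) in the DMSO list (grey) and the abemaciclib list (red), 1 library each. Solid lines count all peaks and dashed lines count peaks that overlap one of the other list; the abemaciclib list is the longer one at each threshold drawn, with 1645 against 434 peaks at a −log10 q of 10.

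The sites occupied in DMSO were for the most part occupied in abemaciclib as well, whereas most sites in the drug-treated cells had no DMSO peak. Of the 971 DMSO peaks, 780 overlapped an abemaciclib peak by at least 1 bp (80.3%, interval 77.7 to 82.8%). Of the 4724 abemaciclib peaks, 778 overlapped a DMSO peak (16.5%, 15.4 to 17.6%) and 3946 did not (83.5%, 82.4 to 84.6%). Random placement of the DMSO regions on their own chromosomes gave a mean overlap of 0.23% and at most 0.824% in 1000 draws. The shares of the lists came closer together among stronger peaks when 1 list was filtered and the whole of the other was kept. All 187 DMSO peaks with a −log10 q of at least 20 were in the abemaciclib list, but only 431 of the 648 abemaciclib peaks at that level were in the DMSO list (66.5%, 62.7 to 70.1%). At a −log10 q of at least 50, all 42 DMSO peaks and 135 of the 141 abemaciclib peaks were shared (95.7%, 91.0 to 98.4%). They did not come closer with both lists filtered at a −log10 q of at least 10, where 92.2% of DMSO and 24.3% of abemaciclib peaks were shared. The shares also depended on list length and on the definition of overlap. With the 971 strongest peaks of each list, 54.7% of the DMSO peaks were shared, and with summits within 100 bp of each other 68.3% were.

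Shared sites had higher folds than the other sites of their list, by the median. Within the abemaciclib list, the median fold was 10.3 (quartiles 7.63 and 14.9) at shared peaks and 5.59 (4.46 and 7.20) at abemaciclib-only peaks. Within the DMSO list, it was 6.58 (5.17 and 8.55) at shared peaks and 4.62 (4.04 and 5.36) at the 191 DMSO-only peaks. Shared regions were also broader than the others of their list, with a median width of 630 bp against 399 bp in abemaciclib and of 456 bp against 384 bp in DMSO. To be shared, a site had to pass the caller in both libraries and overlap. That favours tall and wide peaks, so these differences follow at least in part from the definition.

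Shared sites were ranked by abemaciclib fold, not by pileup. The largest pileups were 486 fragments in the abemaciclib list and 472 in the DMSO list, at sites not named here. The highest fold lay in 8q22.3 (chromosome 8, 102138385 to 102139344), with a fold of 82.6 and a pileup of 261 fragments over a background of 2.17. In DMSO the same site had a pileup of 142 over 7.13. After scaling by the lowest background of each library, its pileup was 2.10 times that in DMSO (interval 1.71 to 2.60). The next was in 12p13.31 (chromosome 12, 6387405 to 6388398), with a fold of 50.5, pileups of 130 in abemaciclib and 76 in DMSO, and a ratio of 1.96 (1.46 to 2.63). A site in 19p13.12 (chromosome 19, 15306190 to 15307348) had a fold of 48.0 and a ratio of 1.67 (1.22 to 2.29). The site in 8q24.13 (chromosome 8, 126441640 to 126443918) had nearly as many fragments in both libraries, 321 in abemaciclib and 314 in DMSO, and its ratio of 1.17 (0.998 to 1.37) did not exceed counting error. Of the other sites among the 10 with the highest fold, that in 17q11.1 (chromosome 17, 25680373 to 25681241) had the highest ratio at 3.90 (2.61 to 5.98). Those in 16p13.3 (chromosome 16, 4994553 to 4996282 and 122047 to 123135), in 5q13.3 (chromosome 5, 73980628 to 73981508) and in 8q24.21 (chromosome 8, 127568997 to 127570855) had ratios between 1.40 and 1.98, all with intervals above 1. The site in 7p13 (chromosome 7, 43622332 to 43623191), with the highest fold of the DMSO list at 32.6, had a ratio of 0.977 (0.751 to 1.27).

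Across shared sites the fragments at the summit were mostly more numerous in abemaciclib. The depth-scaled pileup ratio had a median of 1.38 over the 780 overlapping pairs (log2 0.46, quartiles 0.12 and 0.79), and it was above 1 at 632 of them (81.0%). The interval of the single pair lay above 1 at 225 sites and below 1 at 11. At the 187 sites chosen only for their strength in DMSO, the median ratio was 1.32 and 144 sites were above 1. The median was 1.38 outside the regions chosen to represent DNA amplified in MCF-7 (642 pairs) and 1.35 inside them (138 pairs). Other bands can also hold extra copies, so the outside set is not known to be free of them. Scaling by the estimated read numbers in place of the background gave 1.30.

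**Figure D2:**
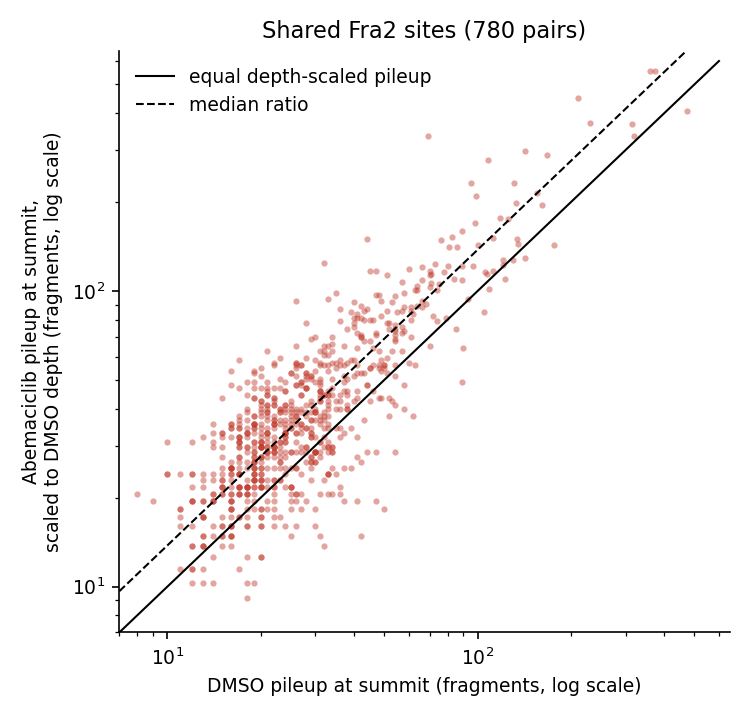
Fragments at the summit of each shared Fra2 site in DMSO (horizontal axis, log scale) and in abemaciclib scaled to the DMSO depth (vertical axis, log scale), with 1 point for each of the 780 overlapping pairs. The solid line marks equal values and the dashed line the median ratio of 1.38; 632 points lie above the solid line.

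At some shared sites the depth-scaled pileup was lower in the abemaciclib library. The interval lay below 1 at 11 of the 780 pairs. Each interval was computed for its pair alone, so among 780 some can lie below 1 by counting error. The 11 pairs therefore do not show a loss of Fra2 at any single site. The sites below were named after their values were seen, among pairs with summits within 100 bp of each other and at least 60 fragments in all. The lowest ratios were 0.366 (0.195 to 0.654) in 10p15.1 (chromosome 10, 5931890 to 5932265), with pileups of 16 in abemaciclib and 50 in DMSO, and 0.530 (0.316 to 0.866) at another site of 10p15.1 (chromosome 10, 3827390 to 3827899). In 5q31.2, the site at 137827420 to 137828177 of chromosome 5 had 43 fragments in abemaciclib and 89 in DMSO, a ratio of 0.553 (0.375 to 0.804). The neighbouring 5q31.2 site at 137800406 to 137801363, second by fold in the DMSO list, had 125 and 177 fragments and a ratio of 0.808 (0.637 to 1.02). Beside the 17q11.1 site, the highest ratios were 3.56 (2.27 to 5.78) in 2q31.1 (chromosome 2, 172963607 to 172964249) and 3.43 (1.95 to 6.34) in 19p13.2 (chromosome 19, 10025142 to 10025905).

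The 10 peaks with the highest fold among those found only in abemaciclib were spread over many chromosomes. The first was in 4p14 (chromosome 4, 36245806 to 36246754), with a fold of 22.4 and 49 fragments over a background of 1.23. It was followed by 22q13.33 (chromosome 22, 50720789 to 50721384), with a fold of 22.4 and 47 fragments, and 22q13.1 (chromosome 22, 39114346 to 39114909), with a fold of 20.0 and 42 fragments. A further 22q13.1 site (39380870 to 39381587) had a fold of 18.8, so that 3 of the 10 were on chromosome 22. The others lay in 3p25.3 (chromosome 3, 11138139 to 11138675), 9q33.2 (chromosome 9, 124043801 to 124044710), 2p24.3 (chromosome 2, 15870379 to 15870997), 8q24.3 (chromosome 8, 142378987 to 142379617), 12q13.13 (chromosome 12, 54812617 to 54813359) and 12q21.31 (chromosome 12, 80580361 to 80580927), with folds from 17.3 to 19.4. No DMSO peak overlapped these regions, which says that the DMSO signal did not pass the caller's threshold there, not that Fra2 was absent. Ranking by fold favours sites with a low background, and the −log10 q of these 10 was at most 55.5. Some abemaciclib-only peaks not named here had a higher −log10 q. At a −log10 q of at least 100, 39 of the 41 abemaciclib peaks were shared.

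The peaks found only in DMSO were few, with a median fold of 4.62 against 5.59 at abemaciclib-only peaks. The median pileup before scaling was 14 fragments in both classes, over median backgrounds of 2.19 in DMSO and 1.47 in abemaciclib. The 5 with the highest fold lay in 19q13.2 (chromosome 19, 39174195 to 39174756), 4q31.3 (chromosome 4, 151383766 to 151384261), 16q12.2 (chromosome 16, 53815024 to 53815470), 20q11.21 (chromosome 20, 30913549 to 30913934) and 18q21.31 (chromosome 18, 55415957 to 55416409). Their folds were between 7.79 and 9.52 and their pileups between 17 and 28 fragments. The lack of an abemaciclib peak at these sites does not say that Fra2 was absent there.

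Fra2 peaks were unevenly distributed over the chromosomes in a similar way in both lists. In abemaciclib the density was highest on chromosomes 20 (4.63 peaks per Mb), 17 (3.97) and 16 (2.76) and lowest on 13 (0.512) and X (0.605). In DMSO it was highest on 20 (1.03) and 17 (1.02). Each chromosome held more abemaciclib than DMSO peaks. The ratio was 9.87 on chromosome 3 (227 against 23 peaks, interval 6.42 to 15.9) and 3.06 on chromosome 19 (153 against 50, 2.21 to 4.30), and those were the only chromosomes whose intervals excluded the overall 4.87. Giemsa-negative bands, the light bands that are rich in genes, make up 42.4% of the assembly. They held 63.9% of DMSO peaks (60.7 to 66.9%) and 63.6% of abemaciclib-only peaks (62.1 to 65.1%). The darkest bands make up 16.4% and held 5.05% (3.76 to 6.62%) and 4.94% (4.29 to 5.66%).

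**Figure D3:**
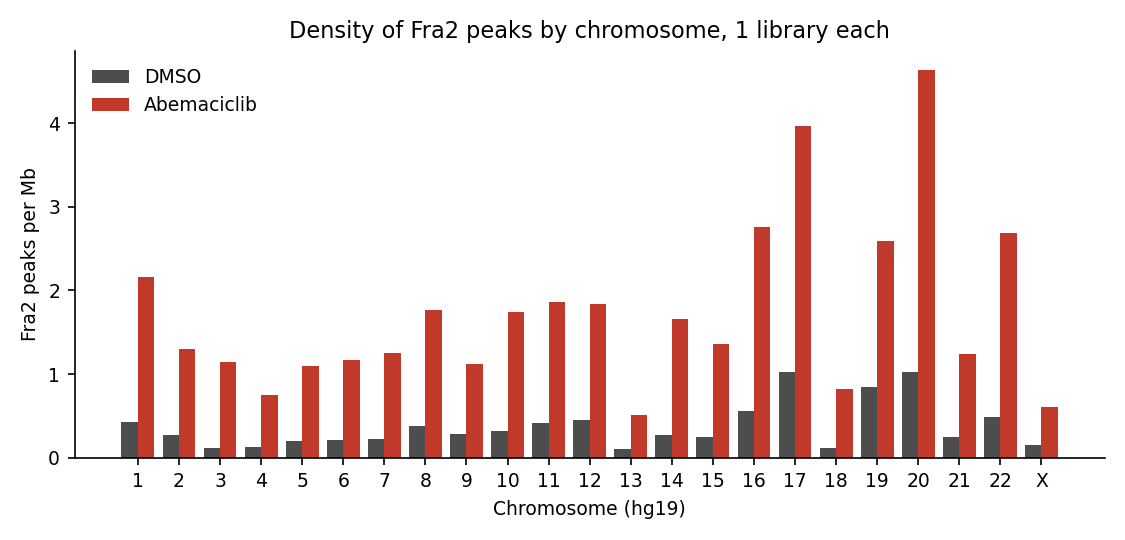
Fra2 peaks per Mb of each chromosome in the DMSO list (grey bars) and the abemaciclib list (red bars), 1 library each, on an axis from 0. The bars are tallest on chromosome 20, at 4.63 in abemaciclib and 1.03 in DMSO.

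MCF-7 cells are known to carry extra DNA copies of parts of chromosomes 1, 3, 17 and 20, and extra copies add background reads to a ChIP library. The regions chosen to represent them (1q, 3p14, 17q22 to 17q25 and 20q13) make up 6.32% of the assembly. They held 156 DMSO peaks (16.1%, 13.8 to 18.5%) and 719 abemaciclib peaks (15.2%, 14.2 to 16.3%), a ratio of 4.61 (3.87 to 5.52). The median recovered background at their peaks was 5.20 fragments in DMSO and 2.69 in abemaciclib, and in 20q13.2 it reached 32.9 and 25.6. Band 20q13.13 held 17 DMSO peaks and 61 abemaciclib peaks, and band 17q23.2 held 14 and 44. Among peaks with a fold of at least 5, the amplified regions held 10.5% of DMSO and 11.6% of abemaciclib peaks. On the chromosomes without these regions, abemaciclib peaks were 4.83 times as many as DMSO peaks (4.45 to 5.25).

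**Figure D4:**
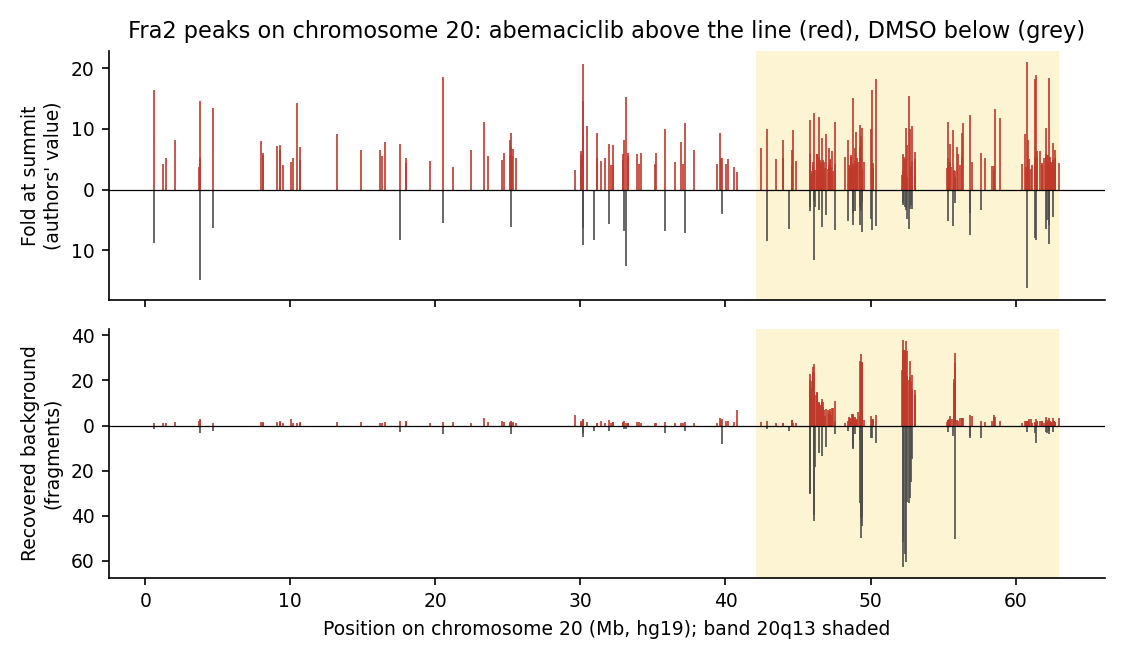
Fra2 peaks along chromosome 20 (Mb, hg19), abemaciclib upward in red and DMSO downward in grey, with band 20q13 shaded. The upper panel gives the authors' fold at the summit and the lower panel the recovered background in fragments; the tall background columns lie within 20q13, where 20q13.2 had median backgrounds of 32.9 in DMSO and 25.6 in abemaciclib.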

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

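No paired analysis was possible because each group holds 1 library. No library could be left out for the same reason, and neither list had regions with several summits to separate. The settings fixed beforehand for promoter shares, motif shares and gene lists were not run, since they need an hg19 genome or annotation. Leaving out chromosomes 1, 3, 17 and 20 kept the ratio of peak numbers and both shared shares within their intervals, and a fold of at least 5 kept the ratio there (4.73). A stricter −log10 q of at least 5 in both lists left 2973 abemaciclib peaks, a ratio of 4.05. The shared shares were then 90.5% of DMSO and 22.3% of abemaciclib peaks. At 10, the lists held 434 and 1645 peaks, a ratio of 3.79, with shared shares of 92.2% and 24.3% and 16.4% of abemaciclib peaks in amplified regions. At a fold of at least 5 the shared shares were 87.2% and 18.4%, and the amplified regions held 10.5% and 11.6% of the peaks. With lists of equal length the shared shares were 54.7% and 54.6%, and 17.9% of abemaciclib peaks lay in amplified regions. A reciprocal overlap of at least 50% gave shared shares of 67.0% and 13.8%, and summits within 100 bp gave 68.3% and 14.03%. The remaining alternatives were chosen after seeing the data. With the lowest DMSO −log10 p as the threshold of both lists the ratio of peak numbers was 4.68. The median pileup ratio at shared sites was 1.47 after subtracting the background and 1.30 when scaled by estimated reads. It was 1.32 at DMSO peaks with a −log10 q of at least 20 and 1.39 at pairs with summits within 100 bp. Outside the amplified regions chosen it was 1.38. Except with lists of equal length, abemaciclib had more peaks in each setting that gave a number of peaks, and each pileup ratio was above 1. The pileup behind a single peak, with medians of 22 fragments in DMSO and 16 in abemaciclib, limits what can be said of single sites. The causes of these shifts were not tested.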

Other observations

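The tests of depth, of the p threshold, of the DMSO background, of DNA copy number under shared sites and of counting error, and the clusters, distances and single bands, were chosen after related values had been seen. Leaving out the chromosomes with amplified regions was planned, but the bound it was held to was set afterwards. Peaks in the drug-treated cells also formed clusters. Summits chained at gaps of up to 12.5 kb gave 60 clusters of 3 or more peaks in abemaciclib and 8 in DMSO. Across 100 random placements of the abemaciclib list the mean was 4.31 and the most 9. The abemaciclib list is longer and the DMSO list was not placed at random, so these counts do not compare clustering between treatments. The placements also ignored regions that are dense in peaks or high in background. The most peaks in a cluster, 9, were in 20q13.31 (chromosome 20, 55731902 to 55773791), where no DMSO peak lay. The background there was high, with a median of 18.1 fragments, and no fold exceeded 3.24. In 8q24.3 (chromosome 8, 144997833 to 145027979), 8 abemaciclib peaks lay within 30.1 kb and none in DMSO, at a median background of 1.51 and folds up to 5.50. In 17q23.2 (chromosome 17, 59470919 to 59494980), 8 abemaciclib and 5 DMSO peaks lay within 24.1 kb, at a median background of 24.0.

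Sites found only in abemaciclib lay closer to DMSO sites than uniform random placement along the chromosomes gives. Of these summits, 4.23% were within 10 kb of a DMSO summit, against a mean of 0.866% and at most 1.34% over 1000 random placements. Within 50 kb it was 12.2%, against a mean of 3.98%. The placements ignored that both lists were concentrated in the same kinds of bands, so closeness beyond that was not tested. Bands at chromosome ends make up 6.40% of the assembly and held 15.6% of DMSO peaks (13.3 to 17.99%) and 13.8% of abemaciclib-only peaks (12.8 to 14.95%). Among single bands, 1q32.1 held 5 DMSO and 51 abemaciclib peaks, a ratio of 10.2 (4.10 to 32.7). Band 9q34.11 had 12 and 20, a ratio of 1.67 (0.776 to 3.74), and was the 1 band of 689 with peaks whose interval excluded the overall ratio.

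The larger number of peaks in abemaciclib has several possible technical explanations. Greater depth is argued against by the ratio of the lowest backgrounds, 0.874. A laxer threshold is argued against by the 4547 abemaciclib peaks that reach the lowest −log10 p of the DMSO list. Extra DNA copies of the chosen amplified regions are argued against by the ratio of 4.83 on the chromosomes without them. A higher background in the DMSO call, as measured at shared sites, would leave 4045 abemaciclib peaks at its median ratio. At its upper quartile it would leave 3395. The ratio of 3.89 needed to account for the difference was reached by 1 of the 780 shared pairs. The DMSO background is known only at sites called in DMSO, so the 3946 abemaciclib-only sites are not covered. A higher DMSO background at those sites is therefore not excluded. A single gain in ChIP efficiency is not excluded: the gain of 1.77 measured at 135 strong sites predicted 1438 DMSO calls among the 1645 abemaciclib peaks with a −log10 q of at least 10, where 645 were seen, a ratio of 2.23 that goes against it by the bound written beforehand. In settings added afterwards, the ratio was 1.98 with the upper quartile of the background ratio, and at a −log10 p of at least 10 it was 1.49 with the median and 1.09 with the upper quartile. A gain of 3.39 was needed for the number seen, where 1.37 was measured at sites chosen by DMSO strength. Choosing sites by strength in 1 library shifts the measured gain towards that library, so this comparison does not decide. The predicted numbers and the needed gain are simulated with an assumed DMSO background at sites that were not called there. They also take each abemaciclib pileup as its true mean, although called peaks are selected for high pileups. An effect of the drug and a difference between single libraries unrelated to it cannot be told apart with 1 library per treatment.

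Local background differed under the same sites. Scaled by the lowest background of each library, it was higher in the DMSO call at 592 of the 780 shared pairs, with a median ratio of 1.32 (quartiles 1.00 and 1.72), which lowers the fold and the −log10 p that a given pileup has in DMSO. The higher background was not confined to the amplified regions chosen, as the median was also 1.32 at the 642 pairs outside them (1.34 inside). This does not decide on DNA copy number, since copies common to both libraries raise both backgrounds. Band 1p13.2, outside those regions, also had high median backgrounds, of 9.87 fragments in DMSO and 4.50 in abemaciclib. Another possible explanation is control reads piled up at the sites themselves. The window of 1 fragment length set the background at 52.9% of 682 shared sites in DMSO (49.1 to 56.7%) and 49.9% in abemaciclib (46.0 to 53.7%). The DMSO share was not above the upper bound of the abemaciclib share, which goes against this explanation by the bound written beforehand. It is not excluded, because the intervals overlap and the same sites were not compared pair by pair. No biological explanation was tested.

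The pileup ratio varied between shared sites. The summed pileups gave a ratio of 1.40 (1.38 to 1.42), and 14.4% of the pairs (11.97 to 17.02%) had intervals that excluded it, 46 above and 66 below; with summits within 100 bp it was 13.7% of 663 pairs. This does not decide whether single sites differed, because the intervals hold counting error only and the spread between libraries of 1 treatment is not known. Counting error, library preparation, duplicate reads and the drug therefore cannot be told apart for sites with fewer fragments after treatment, such as those in 10p15.1 and 5q31.2.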
